A study of Drosophila melanogaster with 3 samples.

How the data were processed

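Binding of Prospero was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Drosophila melanogaster embryos of 2 to 18 h, male and female together. The age is that of the source names, since the age label holds a number of hours that cannot be that of an embryo. The embryos carried a transgene for Prospero fused at its C terminus to green fluorescent protein (GFP), per the labels. The sample descriptions say that an anti-GFP antibody was used, while the antibody label reads pros, and the descriptions were followed here. Chromatin was sheared by sonication to fragments of 200 to 800 bp, per the labels. The labels number 3 biological replicates, which form the single group. No other genotype, stage or antibody was compared, and the control library that the labels name was not used here.

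The deposited files were peak lists in the narrowPeak format on the dm6 build. Per the deposited file descriptions, each replicate has a peak list derived from its own alignments and a control, a further list was derived from the alignments of the 3 replicates pooled, and the optimal set was derived from these lists with a threshold on the irreproducible discovery rate (IDR), a measure of how well peak ranks recur between replicates. The aligner, the peak caller, the read filters and the IDR threshold are not given in the sources used here. Each peak's signal is the value the authors' peak caller gave it, on a scale the sources do not state, so peaks were compared by it only within a list. It served to rank peaks, and at pros also as a ratio and as a median, beside a test on ranks alone. The deposited −log10 q-value of a peak was read to describe the lists and entered no test. In the optimal set it was 4.30 for all 6215 peaks, which was also the highest value of the pooled list, so it gives no order among them. The summit is the position the authors' caller marked inside each peak, deposited as an offset in bp.

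The lists hold no read counts, so the sequencing depth of each replicate is unknown here and no interval that needs it is given. Each replicate list and the pooled list held 30000 peaks, and this equal length means that the number of peaks carries no information on depth or on how much was bound. Exact binomial (Clopper-Pearson) 95% intervals on shares of peaks or genes cover counting error only, and neighbouring peaks are not independent. The labels call the replicates biological without saying how the embryos were collected. P-values from shifted peaks or random gene lists describe these peak lists and not a spread between animals.

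All peaks lay on chromosome arms 2L, 2R, 3L, 3R, 4 and X, and none ran past the end of its arm in the reference. Genes came from the Ensembl annotation, release 115, of the BDGP6 assembly, whose coordinates are those of dm6. Of 13945 protein-coding genes found in both the Ensembl and the RefSeq annotation, 13944 had the same coordinates. Sequence came from the RefSeq copy of the same assembly. Positions are given 1-based.

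Peaks of 2 lists were matched when their summits lay within 150 bp. For overlap between replicates the 6215 strongest peaks of each list were taken, to match the size of the optimal set, and one list was moved 1000 times by random circular shifts within each arm (one-sided permutation test). Each summit was assigned to the first class that applied among promoter (within 500 bp of an annotated transcription start site, TSS), 5′ UTR, 3′ UTR, coding sequence, other exon, intron and intergenic, over protein-coding and non-coding RNA genes. Class shares were tested against 1000 circular shifts (two-sided permutation test, Benjamini-Hochberg adjustment over the 7 classes). A gene counted as bound when a summit of the optimal set lay in its body or up to 1 kb upstream. Each of 17 gene lists was compared with 10000 random lists of protein-coding genes matched in 20 bins of the length of that region (two-sided permutation test, Benjamini-Hochberg adjustment over the lists). The bin that holds pros and other long genes ran from 29.6 to 1967 kb, so long genes were matched only coarsely. Of the listed symbols, 7 were matched through older names, and 2 duplicates were dropped. The lists hold 413 distinct genes, of which 15 are in more than a single list.

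Sequence was searched on both strands in windows of 201 bp centred on the summit and in windows of the same width centred 500 bp to either side. Presence was compared peak by peak with an exact McNemar test against each flank, keeping the larger p, for 11 motifs and for all 2080 distinct 6-mers, with Benjamini-Hochberg adjustment within each family. Summit density on X was compared with that on 2L, 2R, 3L and 3R by permuting 1 Mb bins between X and the autosomes 100000 times. Rank percentiles run to 100 for the strongest peak of a list. The threshold was an adjusted p of 0.05 in each family.

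The tests, gene lists, motifs and most of the alternatives were fixed before the data were examined. The rule for named items took the 15 strongest peaks of the optimal set with the gene of the nearest TSS, the 10 genes with the most summits, and, in each list, the 4 bound genes with the strongest summit and the first 2 unbound genes. It also took pros itself, the 10 enriched 6-mers with the smallest p, and every motif searched. Items named outside this rule are said to be so.

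The tests were tried on simulated data with known answers. With summits unrelated to the annotation, 2.5% of 40 simulated sets were called at promoters, and with 10% of summits moved to a TSS, 100% were. The unrelated sets were themselves circular shifts of the real summits, as in the test, so a low rate of calls was built in. With 50% of 6215 summits shared, the overlap found was 51.3%. Of 500 simulated lists of 25 genes with no raised share, 2.6% were called before adjustment, against 53.6% with the chance of being bound raised 2-fold and 90.4% with it raised 3-fold. Each gene was there drawn as bound on its own, from the share of its length bin. Summits shared by neighbouring genes were not simulated, so false calls of lists with clustered genes were not tested. Of 2080 6-mers, 0 were called with nothing planted, in summit and flank windows all drawn with the base composition of a flank. The higher G and C content of the real summit windows was not simulated, so false calls from it were not tested. With 20 6-mers planted in 4% of windows, 19 were recovered, and the 17 others called all shared 5 bases in a row with a planted 6-mer. For X against autosomes, 5.5% of 200 sets with no difference were called, and 54.5% with X density at 75% of that on autosomes.

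The alternatives tried were other summit distances, promoter widths and window widths, the stronger 50% of the optimal set (3107 peaks), the 3946 peaks present in all 3 replicates, peaks present in both other replicates with each replicate left out, other rules for a bound gene, neighbouring genes of a list within 20 kb counted once, other ways of placing random peaks, and no length matching. For classes, genes, motifs and X, each set with a replicate left out holds the optimal-set peaks matched in both other replicates. These sets of 4421 to 4560 peaks all hold the 3946 and still come from the pooled reads of all 3 replicates. They are stricter filters and not calls made without a replicate. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.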

Results

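Prospero is a homeodomain transcription factor that dividing neuroblasts, the neural stem cells of the fly, pass to their smaller daughter cell. Its binding was mapped in whole embryos of 2 to 18 h through a GFP tag, in 3 biological replicates of a single group. The question the data address is where in the genome, and at which genes, the tagged protein was found. Each replicate had a list of 30000 peaks, and 6215 peaks in 5137 separate regions made up the optimal set that the authors obtained with a threshold on how well ranks recur. These 6215 were also the 6215 strongest peaks of the list called on pooled reads. The lists hold no read counts, so depth is unknown. The signal given per peak is the authors' own, with medians of 36.1, 45.3 and 51.2 in the lists of replicates 1, 2 and 3, on a scale that is not stated, and peaks are compared by it only within a list.

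Most of the strongest peaks recurred between the 3 replicates. Among the 6215 strongest peaks of each list, 74.4% ± 1.32 (SD, 3 pairs of replicates) had a summit within 150 bp in the other list. After circular shifts of the peaks along each arm the share was 1.34%, a 55.7-fold difference (one-sided permutation p = 0.0010, the smallest that 1000 shifts can give). The pair values were 74.5% for replicates 1 and 2, 75.7% for 1 and 3 and 73.1% for 2 and 3. The highest value that any shift gave for the mean of the pairs was 1.85%. The optimal set holds the strongest peaks of the pooled reads of these same replicates, so its match to each is not an independent comparison. Of its peaks, 84.0% ± 1.59 (SD, n = 3) were matched among the 6215 strongest of a replicate, and 63.5% were matched in all 3 (3946 peaks, exact binomial 95% interval 62.3% to 64.7%). With summits required to lie within 50 bp that last share was 37.5%. Only 33 peaks, 0.531%, were matched in none of the 3. Across the 6215 peaks, which are not independent replicates, the ranks of the strongest overlapping peak correlated with a mean Spearman's rho of 0.823 ± 0.0244 (SD, 3 pairs).

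**Figure D1:**
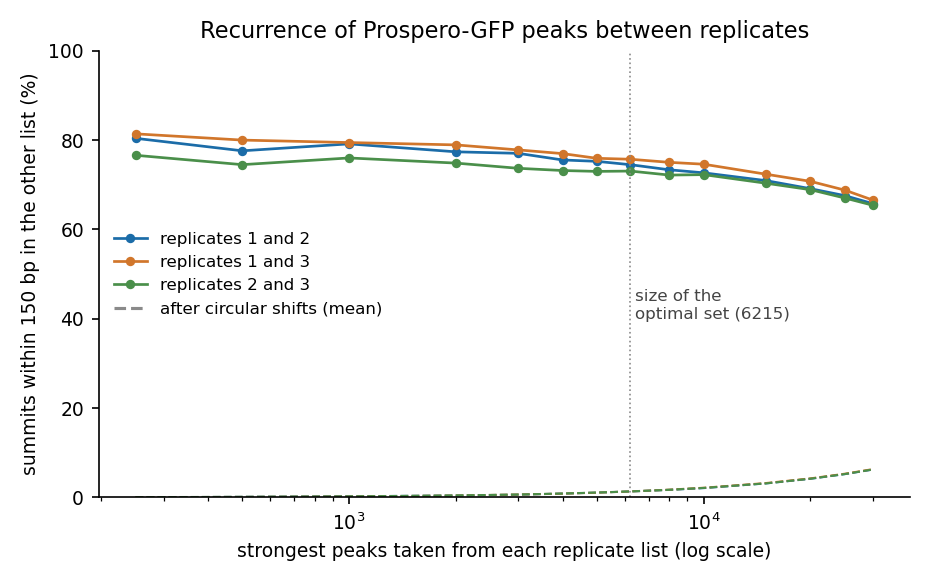
Share of summits (%) with a summit within 150 bp in the other replicate's list, against the number of strongest peaks taken from each list (log scale). Points are pairs of replicates and dashed lines the means after circular shifts, and at 6215 peaks (dotted line) the pairs lie between 73.1% and 75.7%.

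The strongest peaks in the genome lay in a region of 12.1 kb on 2R, from 13559393 to 13571506 (dm6), which was the widest in the optimal set and held 13 of its summits. The region runs from CG13334 to CG42807 and overlaps an annotated INE-1 transposable element. It had the Prospero homeodomain core at 1 of its 13 summits, the strongest. With no control or other GFP library used here, signal of this region in any GFP precipitation was not tested. The top summit, at 13566912, is intergenic and lies 5.63 kb downstream of the CG42807 TSS, with a signal of 24613, and the next, at 13564828, lies 6.28 kb downstream of the CG13334 TSS, with 21450. The summits ranked 5 (13560249, in the CG13334 3′ UTR) and 13 (13570430, intergenic, near CG42807) are in the same region. This region held the strongest peak of every replicate list. The peak ranked 4 lay on 3R at 26006440, 0.417 kb upstream of the TSS of E(spl)mbeta-HLH, a basic helix-loop-helix repressor switched on by Notch. It had a mean rank of 4.33 ± 0.577 (SD, n = 3) in the replicate lists.

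The remaining strong peaks were near genes of several kinds. A summit at 12453337 on 2R lay 0.147 kb into Lac, which encodes the cell adhesion protein Lachesin (rank 7, mean rank in the replicates 9 ± 3.46, SD, n = 3). A summit at 17804842 on 2R lay in an intron of grh (grainy head), a transcription factor of late neuroblasts and of epidermis (rank 9, mean 8.33 ± 1.53, SD, n = 3). Rank 10 was an intergenic summit at 4346922 on 2L, 6.05 kb upstream of CG15429, and rank 11 lay at the promoter of kis, a chromatin remodeller, at 222181 on 2L. Rank 14, at 2123806 on X, was intergenic and 0.52 kb upstream of ph-d, a Polycomb group gene. Rank 15, at 8798038 on 2R, was at the promoter of sns, a cell surface protein of myoblast fusion (mean rank 20.7 ± 10.2, SD, n = 3).

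Peaks were dense at pros, the gene that encodes Prospero. The pros gene (FBgn0004595, 3R 11328480 to 11407627, plus strand, 79.1 kb) held 25 summits of the optimal set, in its body or up to 1 kb upstream, where genes of its length bin had a median of 1. Of the 698 genes in that bin, 3 had as many, pros included. The bin runs from 29.6 to 1967 kb, so its genes match pros only coarsely in length. Several of the 25 pros summits share a peak region, such as those at 11343135, 11343336 and 11343548, so they are not 25 separate regions. The summit of rank 3 in the genome, at 11378865, was in a pros intron 6.08 kb downstream of the nearest TSS, with a signal of 16478, and it ranked 3 in each of the 3 replicate lists. The summit of rank 6, at 11372514, was 0.274 kb upstream of a pros TSS and ranked 6 in each of the 3 lists. Ranks 8 and 12, at 11353365 and 11351905, lay at and within KP78a and KP78b, kinase genes annotated inside a pros intron on the other strand. By position alone, a summit in that stretch cannot be assigned to pros rather than to KP78a or KP78b. In the stronger 50% of the optimal set, pros held 15 summits. The tagged transgene and the resident gene share sequence, so their reads cannot be separated in these lists.

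**Figure D2:**
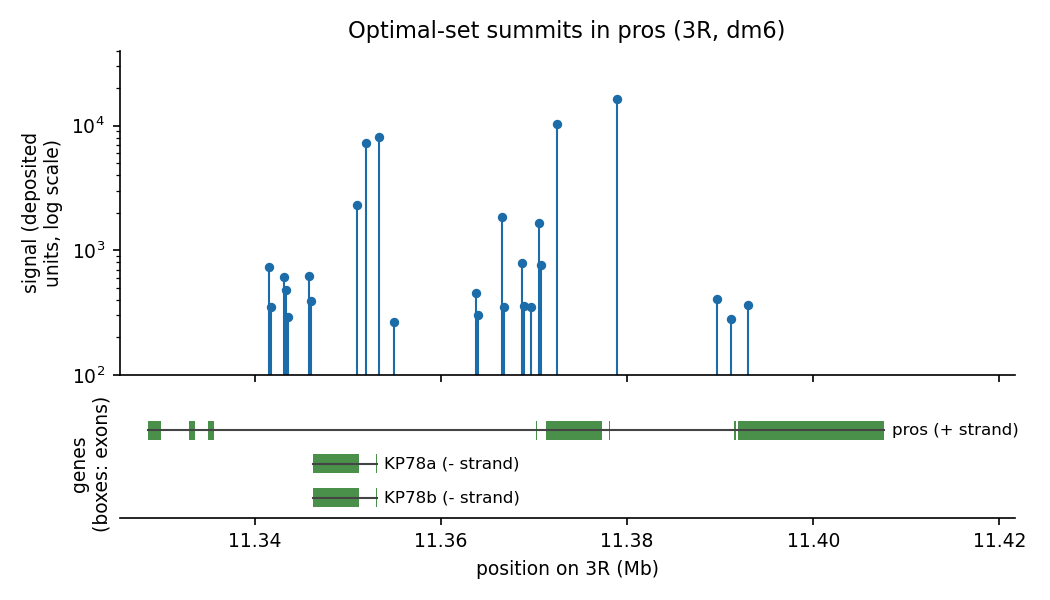
Signal (authors' units, log scale) of each of the 25 optimal-set summits in pros against position on 3R (Mb, dm6), above the annotated exons of pros, KP78a and KP78b (boxes). The highest summits are at 11378865, in an intron, and at 11372514, next to a pros TSS.

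The genes with more summits than pros were jing, a zinc-finger transcription factor, with 32, and hth (homothorax), a homeodomain protein, with 27. After pros came sbb (scribbler), a nuclear regulator, with 23, and Tet, a DNA and RNA dioxygenase, and tara (taranis), each with 22. CG9380, mam (mastermind, a coactivator of Notch) and tou (toutatis, a chromatin protein) had 21 each, and Raf, a kinase of the MAP kinase cascade, had 19. These genes are long and fall in the same wide length bin as pros, where the median was 1 summit. Apart from pros, the strongest of them was tara, whose top summit (intronic, at 16235601 on 3R) ranked 25 in the optimal set and 26.3 ± 2.52 (SD, n = 3) in the replicates. The top summit of jing, intronic at 6613076 on 2R, had a mean rank of 348 ± 48.6 (SD, n = 3).

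Summits were concentrated at promoters and were rare in coding sequence. Promoters held 33.3% of the summits (2071), against 13.1% ± 0.677 (SD of the shifts) after circular shifts, a 2.54-fold difference (two-sided permutation, p = 0.0020, adjusted permutation p = 0.0023). Coding sequence held 0.579% (36 summits) against 13.1%, and 3′ UTRs held 0.901% (56 summits) against 5.03%, each with the same adjusted p of 0.0023. The raw p of 0.0020 is the smallest that 1000 shifts can give. Introns held 42.1% (2616 summits) against 39.4% (adjusted permutation p = 0.022), and intergenic sequence held 20.3% (1264) against 27.8% (adjusted permutation p = 0.0023). Shares in 5′ UTRs (1.22% against 0.770%) and in other exons (1.54% against 0.765%) were higher than after shifts, each with adjusted permutation p = 0.0023. The intron difference was small and did not hold with promoters drawn as 1000 bp from a TSS (35.7% against 36.2%, adjusted permutation p = 0.797) or with 1 summit per peak region (41.5% against 39.4%, adjusted permutation p = 0.076). Against local shifts of 5 to 50 kb the differences for intergenic sequence (20.3% against 21.3%, permutation p = 0.244) and 5′ UTRs (permutation p = 0.062) were also lost. The median distance from a summit to the nearest TSS of a protein-coding gene was 1899 bp, and 29.3% lay more than 5 kb away.

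**Figure D3:**
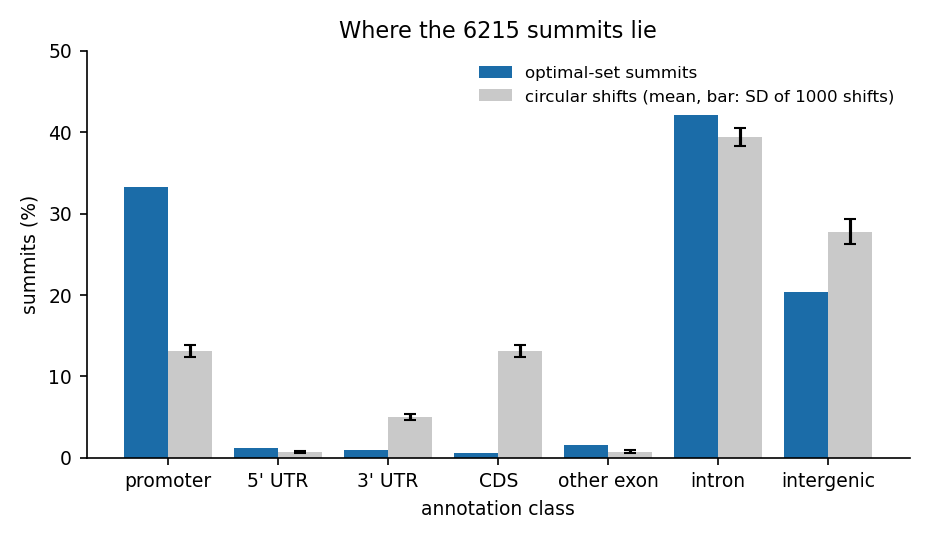
Share of the 6215 optimal-set summits (%) in each annotation class (blue) and the mean after 1000 circular shifts (grey, error bar: SD of the shifts). Promoters hold 33.3% against 13.1%, and coding sequence holds 0.579% against 13.1%.

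Genes for the transcription factors of neuroblasts and neurons were bound far more often than genes of the same length. Of 13945 protein-coding genes, 2502 (17.9%) were bound. Of 25 neuroblast transcription factor genes, 23 were bound (92%, matched mean 24.8%, adjusted permutation p = 0.00068, permutation of random lists). The strongest summits were at grh, at E(spl)mgamma-HLH (promoter, 25999708 on 3R, mean rank 153 ± 45.0, SD, n = 3), at tll (tailless, promoter, 30852036 on 3R) and at nub (nubbin, intron, 12623420 on 2L). The unbound members were ac (achaete), a proneural gene, and hb (hunchback), the first of the temporal series of neuroblast factors. Of the 25 genes on the neuronal transcription factor list, 23 were bound (92%, matched mean 42.2%, adjusted permutation p = 0.00068). The strongest summit of this list was at elav, which is on it though it encodes an RNA-binding protein of neurons (promoter, 520553 on X, mean rank 39.7 ± 9.29, SD, n = 3). Next came zfh2 (promoter, 501699 on 4), jumu (intron, 10354346 on 3R) and lola (intron, 10540622 on 2R, 15 summits in all). The unbound members were ftz and fd59A. In the stronger 50% of the optimal set, 52% of the neuronal factor genes were bound against 29.5% (adjusted permutation p = 0.060).

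The Notch pathway list had 19 of 25 genes bound (76%, matched mean 23.2%, adjusted permutation p = 0.00068). Besides E(spl)mbeta-HLH, the strongest summits were in an intron of neur (neuralized, a ubiquitin ligase for Notch ligands, 9025149 on 3R, mean rank 16.3 ± 1.53, SD, n = 3), and at the promoters of E(spl)m7-HLH (26036636 on 3R) and spdo (sanpodo, 30476438 on 3R). Su(H), the DNA-binding effector of Notch, and H (Hairless) were not bound. Many genes of this list are neighbours in the Enhancer of split and Bearded complexes, and with neighbours within 20 kb counted once, 10 of 15 were bound (66.7%, matched mean 34.7%, adjusted permutation p = 0.025). Of 29 axon guidance and adhesion genes, 22 were bound (75.9%, matched mean 48.6%, adjusted permutation p = 0.0091). The strongest were robo2, a receptor of Slit, with 7 summits, sli, which encodes Slit, with 11, Con (connectin) with 4, and Sema1a, with 13. robo3 and PlexA were not bound. In the stronger 50% of the optimal set the guidance list stood at 55.2% against 34.8% (adjusted permutation p = 0.060).

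Genes of the neuronal function list, which holds synaptic and other neuronal genes, were not bound more often than matched genes. Of 25 neuronal function genes, 10 were bound (40%, matched mean 51.5%, adjusted permutation p = 0.472). After elav, the strongest were cpx (complexin), Gad1, which makes the transmitter GABA, and fne, whose top summits ranked 1038, 1063 and 1161 in the optimal set. Syt1 and Syn, both synaptic vesicle proteins, had none. Of 19 genes for asymmetric division, 9 were bound (47.4%, matched mean 38.1%, adjusted permutation p = 0.629). They included brat, a translational repressor inherited with Prospero, with 16 summits, insc (inscuteable) with 3, numb with 10 and cno (canoe) with 7. The adaptor of Prospero, mira (miranda), named here after its value was seen, had 3 summits. The polarity genes par-6 and pins had none.

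**Figure D4:**
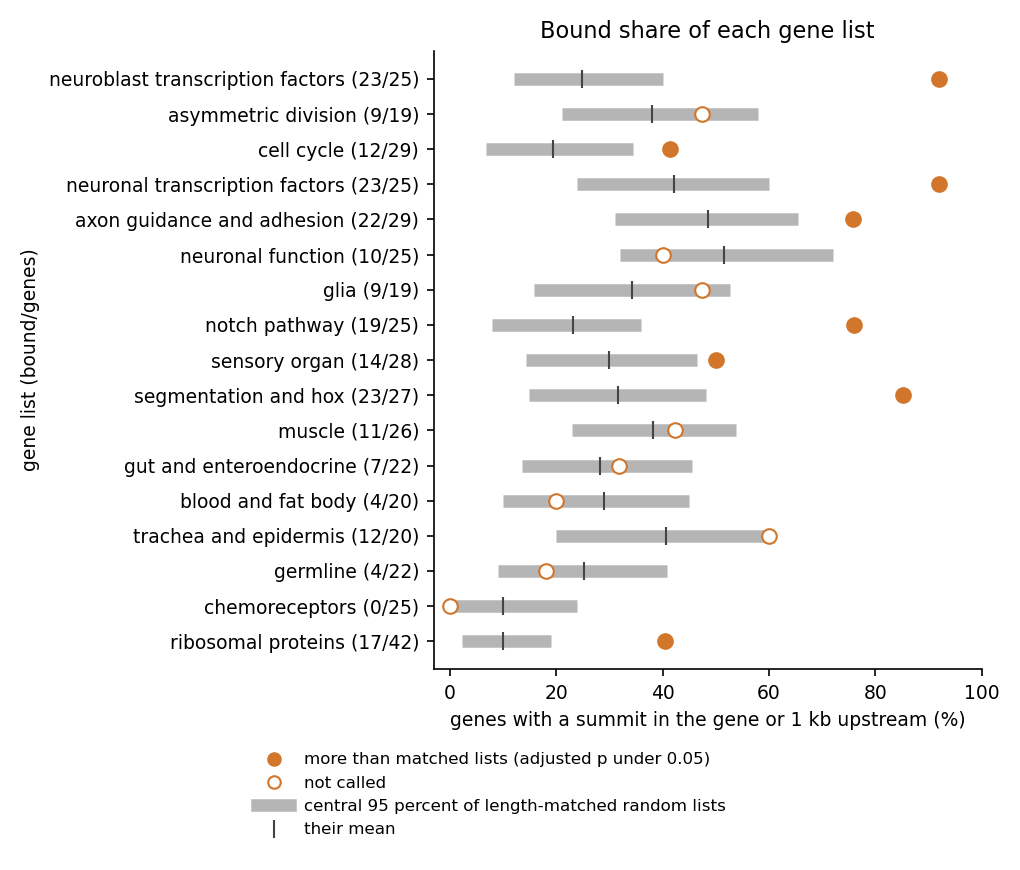
Share of the genes of each list with a summit in the gene or up to 1 kb upstream (%, circles, filled where the adjusted p was under 0.05). Grey bars span the central 95% of 10000 length-matched random lists with a tick at their mean, and the neuroblast and neuronal factor lists stand at 92% against means of 24.8% and 42.2%.

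Among cell cycle genes 12 of 29 were bound (41.4%, matched mean 19.4%, adjusted permutation p = 0.016). The strongest summits were at CycE (promoter, 15731930 on 2L, mean rank 76.7 ± 5.51, SD, n = 3), at E2f1 with 18 summits, at dup, the fly Cdt1, and at fzr, the fly Cdh1. CycB and CycD had none. With a summit required within 1 kb of a TSS, 31.0% of the cell cycle genes were bound against 16.8% (adjusted permutation p = 0.159). Segmentation and Hox genes were bound in 23 of 27 cases (85.2%, matched mean 31.7%, adjusted permutation p = 0.00068). Ubx had 10 summits, Antp had 18, and inv, the sister gene of engrailed, had 5, and tll is on this list too. The pair-rule genes ftz and prd had none.

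The sensory organ list passed the threshold narrowly, with 14 of 28 genes bound (50%, matched mean 30.0%, adjusted permutation p = 0.048). Its strongest summits were upstream of Rh5, a rhodopsin gene (intergenic, 12007510 on 2L), at salm (spalt major), at tap and at sv (shaven). Neither sens (senseless), a zinc-finger factor, nor ato (atonal), a proneural gene, had a summit. The call ended in 6 of 10 alternatives. Among them was each smaller set of optimal-set peaks matched in both other replicates, with a replicate left out. These sets overlap and still rest on the pooled reads of all 3 replicates. There the share was 39.3% against a matched mean of 24.9% without replicate 1, 42.9% against 25.3% without replicate 2 and 39.3% against 24.7% without replicate 3. Of 42 ribosomal protein genes, 17 were bound (40.5%, matched mean 9.96%, adjusted permutation p = 0.00068). The strongest were RpL11, RpS4, RpL13 and RpL8, each with 1 promoter summit, at ranks 1928, 2270, 2511 and 2607 of the optimal set. RpL5 and RpL6 were not bound. In the stronger 50% of the optimal set 14.3% of the ribosomal protein genes were bound against a matched mean of 4.4% (adjusted permutation p = 0.057). Without replicate 1, among peaks present in the other 2 replicates, 16.7% were against 6.6% (adjusted permutation p = 0.075).

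The remaining lists, for glia, for tissues outside the nervous system, for the germline and for chemoreceptors, did not pass the test. Muscle genes were bound in 11 of 26 cases (42.3%, matched mean 38.2%, adjusted permutation p = 0.851), led by sns, kirre, Tm1 and mbc, and the mesoderm factors twi and bap had none. Glial genes were bound in 9 of 19 cases (47.4%, matched mean 34.3%, adjusted permutation p = 0.472), led by nrv2, pnt, ttk and loco, and the glial regulators gcm2 and repo had none. Tracheal and epidermal genes were bound in 12 of 20 cases (60%, matched mean 40.7%, adjusted permutation p = 0.215), led by grh, the chitin genes knk and kkv, and trh, with btl and serp unbound. This list passed the test in 4 of 10 alternatives, for example in the stronger 50% of the optimal set (60% against 28%, adjusted permutation p = 0.0082). Gut and enteroendocrine genes were bound in 7 of 22 cases (31.8%, matched mean 28.2%, adjusted permutation p = 0.853), led by peb, Dll, lab and grn, with GATAe and byn unbound. Blood and fat body genes were bound in 4 of 20 cases (20%, matched mean 29.0%, adjusted permutation p = 0.629), which were ush, with 17 summits, kn, srp and gcm. The blood genes lz and Hml had none. Germline genes were bound in 4 of 22 cases (18.2%, matched mean 25.2%, adjusted permutation p = 0.679), which were Sxl, gcl, mei-W68 and vas, with nanos and osk unbound. Chemoreceptor genes, Orco and Or22a among them, were bound in 0 of 25 cases (exact binomial 95% upper limit 13.7%, matched mean 10.1%, adjusted permutation p = 0.236).

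The DNA core bound by the Prospero homeodomain was more frequent at summits than in their flanks. AAGACG, or its reverse complement CGTCTT, was in 11.3% of the summit windows (exact binomial 95% interval 10.5% to 12.1%) and in 5.13% of the flanking windows, a ratio of 2.20 (exact McNemar, p = 3.8e-34, adjusted exact McNemar p = 2.1e-33). Counts per 20 bp bin were highest 20 bp to the left of the summit, at 0.933 per kb. Among the 1243 strongest peaks of the optimal set, 16.3% of windows had the core (flanks 5.15%), and among the 1243 weakest 9.25% did (flanks 4.63%). Of the 59 other 6-mers made of the same bases, none had a ratio as high. Their median ratio was 1.19 and the highest 1.73. The degenerate site CWYNNCY was in 94.8% of the summit windows and in 89.3% of the flanks (ratio 1.06, adjusted exact McNemar p = 6.6e-29).

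**Figure D5:**
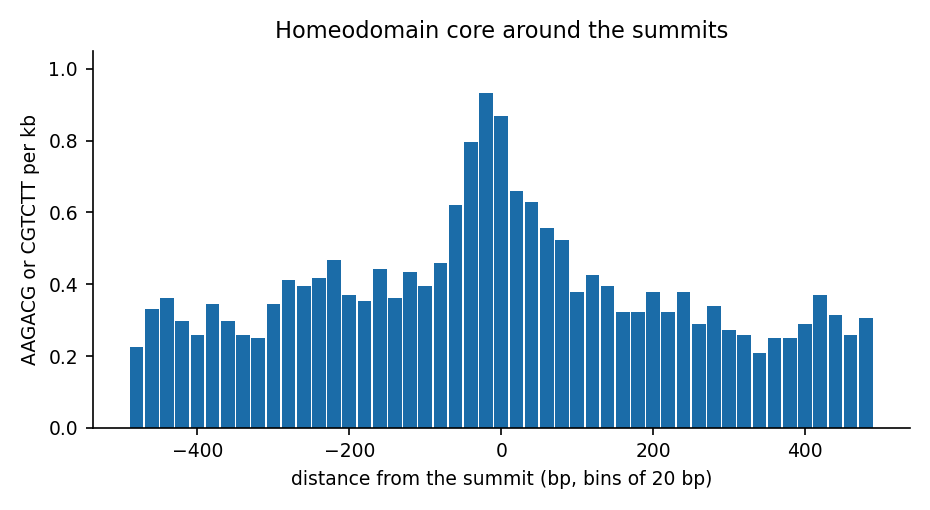
Occurrences of AAGACG or CGTCTT per kb in bins of 20 bp, against the distance of the bin from the summit (bp), over the 6215 optimal-set summits. The highest bin, at −20 bp, stands at 0.933 per kb.

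Sites of several other factors were also more frequent at summits. The GAGA repeat GAGAGA, a site of GAGA factor at open chromatin, was in 19.9% of summit windows against 8.74% (ratio 2.27, adjusted exact McNemar p = 4.3e-72). CAGCTG, an E-box bound by basic helix-loop-helix factors, had a ratio of 1.46 (11.6% against 7.96%, adjusted exact McNemar p = 2.1e-11). CAGGTA, the site of the early factor Zelda, had a ratio of 1.39 (adjusted exact McNemar p = 0.00019), and ACCGGTT, a Grainy head site, 1.61 (1.48% against 0.917%, adjusted exact McNemar p = 0.018). The homeodomain core TAATTA was rarer at summits than in flanks (7.58% against 14.4%, ratio 0.525, adjusted exact McNemar p = 2.6e-31). TGATAA, for GATA factors, and ATTGTT, for Sox factors, were also rarer (ratios 0.803 and 0.812, adjusted exact McNemar p = 4.8e-05 and 9.1e-08). The Tramtrack and DREF sites did not differ (adjusted exact McNemar p = 0.248 and 0.550). Summit windows held 45.8% G and C, against 39.7% and 39.5% in the flanks, and no ratio was adjusted for this difference.

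Of all 2080 6-mers, 687 were more frequent at summits and 528 less frequent. CACCCC had the smallest p, in 17.7% of the summit windows and 5.55% of the flanks (ratio 3.19, adjusted exact McNemar p = 3.0e-97). Related C-rich sequences followed, CAACCC (ratio 2.73), CCACCC (2.51) and ACCCCC (2.69), with sequences rich in G and A, AGAGAG (2.31), GAGAGA (2.27), GAGCGA (2.34), AGAGCG (2.30), GAGAGC (2.19) and AGAGGG (2.41). The Prospero core was at position 30 of the 687 by p and at 24 of 2080 by ratio.

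The X chromosome, present once in males, held 40.3 summits per Mb and the large autosomes 47.7 (ratio 0.846, permutation p = 0.222 over 24 X and 112 autosomal bins). In simulated data with X density at 75% of that on autosomes, the test called 54.5% of sets, so a difference of this size could be missed. Leaving out bins with no peak in the pooled list gave 0.767 (permutation p = 0.024). Promoter peaks were neither stronger nor weaker than other peaks beyond the spread between replicates. The median rank percentile of promoter peaks minus that of other peaks was 0.30 ± 1.11 (SD, n = 3), with values of −0.40, −0.28 and 1.58 in replicates 1, 2 and 3. The sign of the mean rests on replicate 3, since without it the mean is −0.34. It rests on the promoter width too, since with a TSS distance of 200 bp the mean was −0.88. An exact sign test on 3 values cannot give a two-sided p below 0.25.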

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

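All tests on the regulator genes of other tissues, the tests on rRNA and small nuclear RNA genes, the test on ranks at pros and the removal of optimal-set regions from the replicate lists were chosen after results were seen. The tests on tRNA genes, on the core at ribosomal protein promoters and on signal at the pros locus were set out before their own results were known.

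Replicate peaks past the size of the optimal set also recurred. Among replicate peaks ranked 6216 to 12430, just past the size of the optimal set, 54.8% ± 0.656 (SD, 3 pairs) had a summit within 150 bp among the 12430 strongest of the other replicate, against 2.65% after 100 circular shifts, with 3.46% as the highest shift. Some of these peaks lie in regions of the optimal set. With every peak that overlaps such a region left out of both lists, 47.6% ± 1.68 (SD, 3 pairs) recurred, against 1.13% after shifts, with 1.67% as the highest shift. They are listed because the genes, classes and motifs of the report were taken from the optimal set alone, and these peaks lie above the level of shifted peaks.

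Ribosomal protein genes were bound in 40.5% of cases against 9.96% of matched genes. A candidate technical explanation is signal at strongly transcribed promoters whatever protein is tagged. tRNA genes, which are also strongly transcribed, had a summit within 500 bp in 14.8% of 290 cases against 6.62% after local shifts (permutation p = 0.0020, the smallest that 1000 shifts can give). This explanation predicts such an excess. Promoters as a class held 33.3% of all summits against 15.6% after local shifts. The tRNA share therefore cannot tell strong transcription from the general excess at promoters. As for sites with the homeodomain core, 0% of 18 ribosomal protein promoter summits had the core against 10.2% of 2053 other promoter summits, and 18 are too few to decide (one-sided Fisher's exact p = 0.145). Genes for small nuclear RNAs had a summit in 16 of 32 cases against 7.54% after local shifts (adjusted permutation p = 0.0033). rRNA genes had one in 0 of 99 against 7.05% (adjusted permutation p = 0.242), and whether reads of near-identical copies were kept is unknown. No control library was used here, so the cause stays open.

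Some of the strongest peaks in the genome were in pros, the gene carried by the transgene, and extra copies of the locus are a candidate technical cause. The strongest pros peak stood 96.0-fold over the median pooled-list peak of the gene, against a 95th percentile of 16.9-fold in 615 genes with at least 10 pooled-list peaks. By ranks, 107 of these genes had a median peak as high as that of pros and 0% of them a strongest peak as high. Neither comparison can decide. The gene pros was singled out for its strongest peaks, and only 2 peaks rank above the strongest of these. No gene has the median that would bring the fold under that limit. The median pooled-list signal in pros, 171.6, lay between the median of those genes (121.6) and their 95th percentile (261.4), so extra copies, a raised signal over the whole locus and binding of Prospero to its own gene all stay open.

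Neuroblast and neuronal factor genes were bound more often than matched genes, which could reflect regulator genes of any tissue. A choice of 20 transcription factor genes of mesoderm, gut, blood, trachea and early patterning gave 55% bound against 36.4% of matched genes (permutation p = 0.101), a lower share than the 92% of neuroblast factors (Fisher's exact p = 0.0059), but these 20 were picked by hand with the bound genes known. All 42 transcription factor genes of the muscle, gut, blood, trachea and segmentation lists that are on neither neural factor list were then taken. Of these, 76.2% were bound against 37.7% (permutation p = 2.0e-04, the smallest that 10000 lists can give). Binding at regulator genes of any tissue predicts this. These 42 include gcm, also on the glia list, and genes of the segmentation and Hox list, itself at 85.2%. They were not chosen to lack a role in the nervous system, so their share cannot decide. The neuroblast factors did not differ from these 42 past the threshold (Fisher's exact p = 0.186). Neither Fisher's test takes gene length into account. The matched mean was 24.8% for the neuroblast factors, 36.4% for the 20 and 37.7% for the 42. A higher share at neural factor genes was therefore neither shown nor excluded. The embryos were taken whole, so the cells in which any gene was bound are unknown.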

How the results depend on the processing

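Local shifts, 1 summit per region, protein-coding genes alone, neighbouring list genes counted once, rank by summit within 150 bp and bins with a pooled-list peak were chosen after the data were seen. Of 251 values recomputed for 28 results, 216 kept their direction and side of the threshold, or stayed within the spread or within 1.5 times a count. Promoter enrichment (19.8% to 44.4% of summits, always past the threshold), the overlap between replicates (50.3% to 82.6%), the Prospero core (ratio 1.46 to 3.02) and the count of enriched 6-mers (542 to 706) did so in every alternative. So did the neuroblast factor, Notch pathway and segmentation and Hox lists, 3 of the 8 called, in all 10 alternatives. Where a result changed, the cause was not tested, except that smaller peak sets bind fewer genes by construction.

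Peaks present in all 3 replicates moved to 37.5% with summits within 50 bp, 74.9% within 500 bp, 92.9% in the stronger 50% of the optimal set, and 71.1% to 73.4% with a replicate left out. A wider distance or fewer replicates to match cannot lower this share, nor can a narrower distance raise it. The stronger 50% was still matched among the 6215 strongest peaks of each replicate. The mean rho was 0.652 with ranks taken from summits within 150 bp, and 0.801 to 0.849 with a replicate left out. The intron share fell below its shifted value with a TSS distance of 1000 bp (35.7%) and was 41.5%, past the threshold no longer, with 1 summit per region. The promoter rank difference was −0.88 with a TSS distance of 200 bp. X density relative to autosomes was 0.767 (permutation p = 0.024) in bins with a pooled-list peak.

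In the stronger 50% of the optimal set, 5 lists were called in place of 8. Calls ended for neuronal factors (52% against a matched mean of 29.5%), axon guidance (55.2% against 34.8%), sensory organ (28.6% against 19.7%) and ribosomal proteins (14.3% against 4.4%). A call was gained for trachea and epidermis (60% against 28%), and pros held 15 summits. Among peaks present in all 3 replicates the sensory organ call ended (35.7% against 23.2%) and the tracheal list was called (60% against 32.7%). With a summit required within 1 kb of a TSS, calls ended for cell cycle (31.0% against 16.8%) and sensory organ (42.9% against 23.3%). By the gene of the nearest TSS the tracheal list was called (65% against 37.7%). Which genes count as bound also depends on that rule. By it the neuroblast factors stood at 96% against 24% and the chemoreceptors at 12% against 10.8%. With a replicate left out of the matching, the sensory organ share was 39.3% to 42.9%, against matched means of 24.7% to 25.3%, and never called. The ribosomal protein share was 16.7% against 6.6% (without replicate 1, not called) to 23.8% against 6.6% (without replicate 2). Without length matching, 13 lists were called as more bound, among them asymmetric division (47.4%), neuronal function (40%), glia (47.4%), muscle (42.3%), and trachea and epidermis (60%), and chemoreceptors (0%) were called as less bound. The depth of the libraries is unknown and its effect was not examined.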

Other observations

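All tests in this part were chosen after the planned results were seen. The Enhancer of split complex, a cluster of Notch-responsive genes on 3R from 25997621 to 26041008 (dm6), was bound almost throughout. Its 43.4 kb held 33 summits, and 10 of its 11 genes were bound. The complex was singled out after most of its genes had been seen bound in the Notch list, and its genes share summits, so no test is given. Of 13 gene families compared with length-matched random lists, 4 were bound less often and 0 more often. Of 32 genes of the dpr and DIP families, surface proteins by which neurons recognise partners, 5 were bound (15.6% against 48.0%, adjusted permutation p = 0.0026), and of 14 genes of the beaten path family 2 were (14.3% against 54.1%, adjusted permutation p = 0.019). Cytochrome P450 genes were bound in 2 of 85 cases (2.35% against 13.9%, adjusted permutation p = 0.0026) and ionotropic receptor genes in 1 of 60 (1.67% against 13.8%, adjusted permutation p = 0.014). The other 9 families did not pass. Among them were 12 of 44 translation initiation factor genes (27.3% against 17.0%, adjusted permutation p = 0.150), 9 of 73 mitochondrial ribosomal protein genes (12.3% against 6.99%, adjusted permutation p = 0.174) and 2 of 48 proteasome genes (4.17% against 8.99%, adjusted permutation p = 0.422).

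Annotated RNA genes and transposable elements were counted by class, and the classes were not tested against each other. Genes for small nuclear RNAs, the RNA parts of the splicing machinery, had a summit within 500 bp in 16 of 32 cases (50% against 7.54% after local shifts, adjusted permutation p = 0.0033 over 5 classes). tRNA genes had one in 43 of 290 cases (adjusted permutation p = 0.0033), small nucleolar RNA genes in 23 of 269 (8.55% against 5.51%, adjusted permutation p = 0.242), and rRNA genes in 0 of 99 (against 7.05%, adjusted permutation p = 0.242). Transposable elements had one in 118 of 5809 cases (2.03% against 4.92%, adjusted permutation p = 0.0033). The read filters are not given, so whether reads of repeated copies, as of transposable elements and rRNA genes, were kept is unknown.

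Of 11 motifs, 3 differed in frequency between promoter and other summits. GAGAGA was in 26.6% of promoter summit windows, 17.8% of intron windows and 13.1% of intergenic windows, with an adjusted Fisher's exact p of 4.9e-19 for promoter against other summits. The others were the DREF site (1.21% at promoters and 0.229% in introns, adjusted Fisher's exact p = 3.8e-06) and the degenerate Prospero site (93.3% and 95.6%, adjusted Fisher's exact p = 0.0012). For all 3 motifs the flanking windows had the same order, which was not tested. The values there were 1.38% and 0.440% for the DREF site and 88.9% and 90.2% for the degenerate site. For GAGAGA the flanks held 9.63% at promoters, 9.35% in introns and 6.33% in intergenic sequence. The Prospero core was in 10.1% of promoter windows, 12.0% of intron windows and 10.6% of intergenic windows, with no difference between promoter and other summits past the threshold (adjusted Fisher's exact p = 0.125). Relative to the flanks its ratio was 1.75 at promoters, 2.39 in introns and 2.55 in intergenic sequence. In the region of 12.1 kb on 2R with the strongest peaks, 1 of the 13 summits had the core in its window. It was the strongest summit of the optimal set, in which 11.3% of all summit windows had the core.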
